A study of Mus musculus with 20 samples.

How the data were processed

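Liver RNA from 20 male C57BL/6 mice was hybridised to Affymetrix Mouse Gene ST arrays, 1 array per mouse. The labels place 5 mice in each of 4 groups after 7 weeks: a standard diet (SD), a high-fat diet (HFD), and each of these diets with a daily oral dose of 1000000000 colony-forming units of Bifidobacterium pseudocatenulatum CECT 7765 (SD+P and HFD+P). Each array carries a mouse number in its label, and each mouse is named here by its group and that number. Neither the labels nor the value table gives a scan date or batch, so batches were not tested.

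The deposited values are intensities on a linear scale, 1 per probe set and array, made by RMA in Affymetrix Expression Console 1.1.2, per the submitters' processing notes. RMA corrects the background, quantile normalises the arrays and summarises the probes of a probe set. The deposited intensities ran from 3.91 to 9986, and the median intensity per array lay between 28.5 and 30.4. The design of the tests had assumed log2 values. The log2 of each deposited intensity was therefore taken first, and all tests ran on that scale with no pseudocount. Because RMA gives each array nearly the same distribution, a shift of most transcripts in 1 direction cannot be seen in such values.

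The value table held 28361 probe sets. The platform annotation paired 21780 of them with 1 gene symbol, 1617 with several and 4964 with none, and only probe sets with 1 symbol were named. Symbols were updated through Entrez identifiers, of which 21689 matched the RefSeq gene table of GRCm38.p6. That table was used for names and genomic lengths only, and no coordinates are given because the sources used here name no genome build for the arrays. Of the 19934 genes, 996 had more than 1 probe set, and the probe set with the highest mean over all arrays was kept. The 25% of genes with the lowest mean were left out, at a limit of log2 3.70, which left 14950 genes. Closely related genes, such as members of the Cyp2b, Cyp4a, Gstm and Hspa1 families, can share probes on this platform, so their values are open to cross-hybridisation.

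Groups were compared with limma 3.58.1 in R 4.3.3. A single fit of the 4 group means to all 20 arrays, with 16 residual degrees of freedom, gave every contrast, with eBayes moderation and a mean-variance trend. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The series design names 3 comparisons: HFD with SD, HFD+P with HFD, and SD+P with SD. The comparison of HFD+P with SD+P and the interaction, which is the probiotic effect on the high-fat diet minus that on the standard diet, were added before the data were examined. So were the 32 gene lists, with 779 entries, of which 652 were tested, and the rule for naming genes.

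Lists were tested with camera at a preset inter-gene correlation of 0.01, with adjusted p over the 32 lists. Each call was repeated with a correlation estimated from the data and with fry. The level of a list in an array is the mean over its members of the log2 value minus the gene's mean over all arrays. An exact permutation test of these levels between 2 groups of 5, two-sided, was added after seeing the data, and the smallest p it can give is 0.0079. Counts described as adjusted over the list alone use the Benjamini-Hochberg correction within that list. The median, the mean and the direction of the test differed in sign for some lists, none of them called, among them the glucose list and the adipocyte markers between HFD and SD.

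Named genes were chosen by this rule: in each of the 3 comparisons, the 8 largest rises and 8 largest falls among called genes, leaving out unnamed, predicted and olfactory genes. Where fewer than 12 genes passed, those with the smallest unadjusted p were named to reach 12, as values without a call. The 3 members with the smallest unadjusted p were named for each list called. Lipid, glucose and inflammation genes were also fixed in advance, among them Srebf1, Fasn, Scd1, Cd36, Cidea, Cpt1a, Cyp4a14, Cyp7a1, Pck1, Saa1, Tnf, Tlr4 and Adgre1. Of these, Cidea lay under the limit for dim genes. For the interaction and for HFD+P against SD+P, the 5 genes with the smallest unadjusted p were named.

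The fit was tested on simulated data with 14950 genes, of which 100 had been changed by 1.5-fold and a further 100 by 2-fold. For HFD against SD it recovered 79.0% of the 1.5-fold and 97.0% of the 2-fold changes. For HFD+P against HFD the shares were 85.0% and 97.0%, and for SD+P against SD 72.0% and 95.0%. False calls were 5.4%, 5.7% and 6.2% of all calls in these 3 comparisons, and 7.8% for HFD+P against SD+P. The simulated noise was independent between genes, with 1 spread per gene in all groups. In the data, deviations from the group mean had a standard deviation of 0.267 and 0.282 in HFD+P mice 6 and 8, against at most 0.204 elsewhere. The shares recovered can therefore be too high, and the shares of false calls too low, for the real arrays. Correlations are across genes, which are not independent replicates. The number of arrays, 5 per group, limits the precision of every value.

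Alternatives were the filter on dim genes, the variance model, the arrays in the fit, array weights, the mouse number as a replicate block, 2 further normalisations, every probe set in place of 1 per gene, a fold minimum of 1.2, and each array left out in turn. Removing from each array its smooth trend with gene length, and leaving out arrays that stood apart, were added after seeing the data. Regroupings of the arrays, 100 per comparison, tested each count of calls. Figures were drawn with matplotlib 3.10.9.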

Results

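Gene expression was measured in the livers of 20 male C57BL/6 mice, 5 in each of 4 groups, after 7 weeks on a standard diet (SD) or a high-fat diet (HFD), with or without a daily dose of the probiotic Bifidobacterium pseudocatenulatum CECT 7765 (P). The arrays were closely alike: the highest correlation of an array with any other ranged from 0.9914 to 0.9963 across the probe sets. The lowest of these values belonged to HFD+P mouse 6, at 0.9914, and HFD+P mouse 8, at 0.9920. All comparisons below are log2 differences between group means, with the standard error (SE) from limma.

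The first comparison asked what the high-fat diet did to the liver transcriptome. The largest log2 difference was that of Cyp2b9, a cytochrome P450 gene with female-biased expression in mouse liver, at 3.43 (SE 0.57). Its mean of log2 3.22 in SD mice lay under the log2 3.70 limit for dim genes, so the difference is not a measured fold change. Mfsd2a, a transporter of lysophosphatidylcholine, was 6.61-fold higher (2.72, SE 0.34), and the fatty acid transporter Cd36 was 2.20-fold higher (1.14, SE 0.16). The largest falls were those of the fatty acid-binding protein gene Fabp5 (-2.38, SE 0.33) and the adhesion receptor gene Adgrf1 (-2.20, SE 0.28). By camera, genes of cholesterol synthesis fell as a list, and genes of fatty acid oxidation, lipid droplets and heat shock rose. None of these lists passed with an estimated correlation, where the smallest adjusted p was 0.0804.

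In all, 313 of 14950 genes changed between HFD and SD (limma, adjusted p under 0.05), of which 117 rose and 196 fell. At least 2-fold changes were seen in 14 of the genes that rose and 19 of those that fell. Besides Cyp2b9, Mfsd2a and Cd36, the largest rises were in Cyp4a31 (1.56), the pantetheinase gene Vnn1 (1.34), the inducible heat shock protein gene Hspa1a (1.22), Alas1 (1.2), which encodes the rate-limiting enzyme of haem synthesis, and Acnat2 (1.15). After Fabp5 and Adgrf1, the largest falls were in the nicotinic receptor subunit gene Chrna4 (-2.05), the serine protease gene Prss8 (-1.62), Cib3 (-1.56), the immediate early transcription factor gene Egr1 (-1.48), Csad (-1.47), which encodes an enzyme of taurine synthesis, and Cyp2c55 (-1.42), whose mean of log2 3.58 in HFD mice lay under the limit for dim genes. Prss8 had the smallest adjusted p of all genes, 8.69e-06. With 1 of the 10 arrays left out in turn, the calls of Cyp4a31, Alas1 and Acnat2 were lost for 8 arrays each and that of Egr1 for 9. Cyp2b9 varied widely among HFD mice, at log2 6.64 ± 1.57 (standard deviation, n = 5) against 3.22 ± 0.09 (standard deviation, n = 5) on the standard diet.

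**Figure D1:**
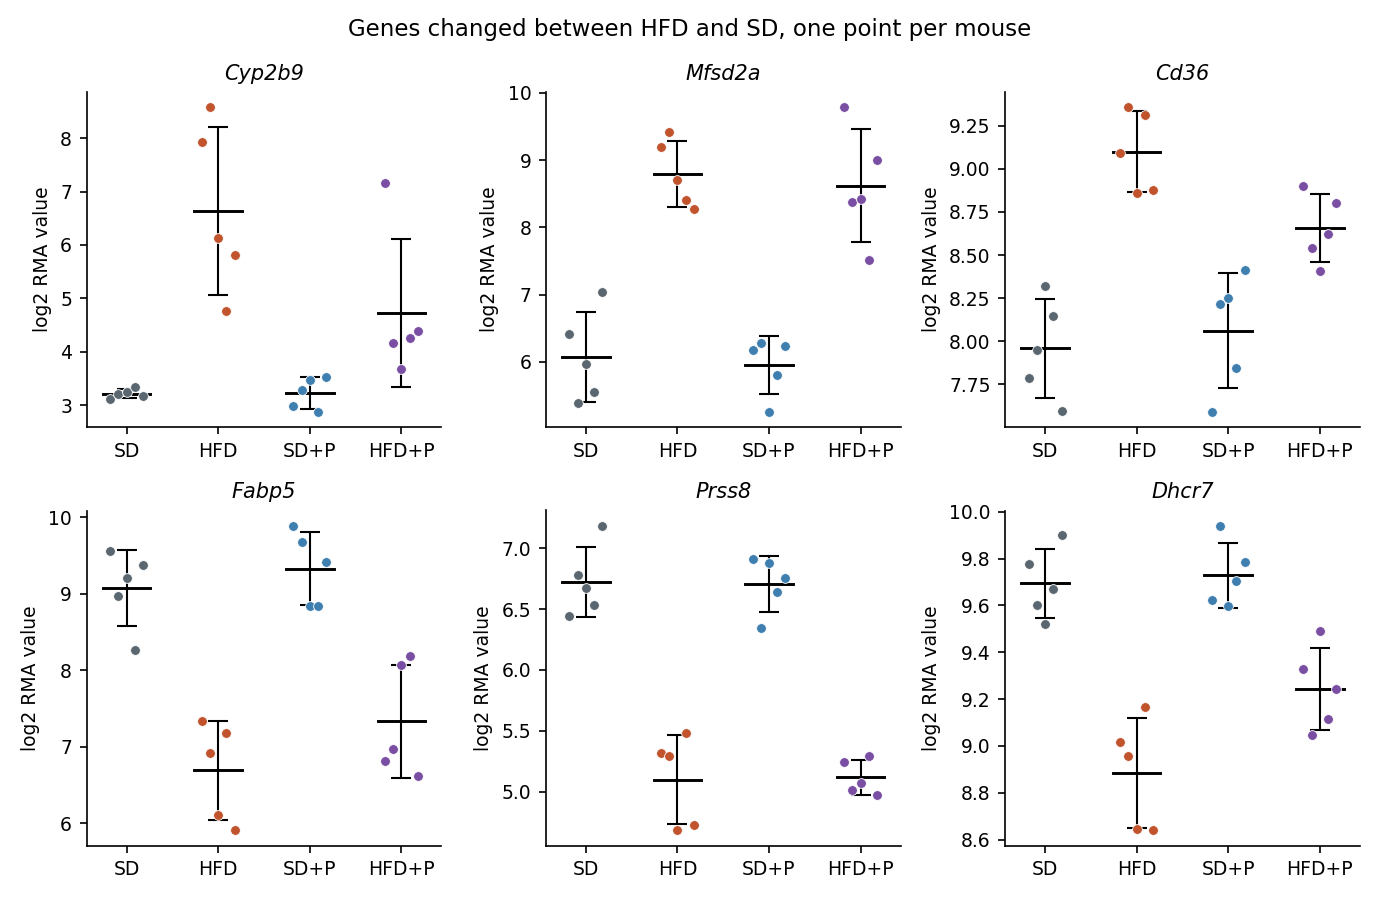
Log2 RMA values of 6 genes (vertical axis) in each of the 4 groups (horizontal axis); each point is 1 mouse, the horizontal line is the group mean and the bar is 1 standard deviation (n = 5). Prss8 lies between 6.45 and 7.18 in SD mice and between 4.68 and 5.48 in HFD mice, with no overlap.

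Genes for cholesterol synthesis and uptake were lower on the high-fat diet. Of 20 measured members, 13 fell, 0 rose and 7 did not pass, and 18 fell when adjusted over the list alone. The median log2 change was -0.71. Dhcr7, which encodes the last enzyme of the Kandutsch-Russell pathway, changed by -0.81 (SE 0.11), Fdps, the farnesyl diphosphate synthase gene, by -0.84 (SE 0.13), and the mevalonate kinase gene Mvk by -0.62 (SE 0.11). The list passed camera at an adjusted p of 1.19e-22, and had an adjusted p of 0.0804 with an estimated correlation. Its level was lower in each HFD mouse than in each SD mouse (exact permutation p = 0.00794, 0.0847 adjusted over 32 lists).

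Fatty acid oxidation and ketogenesis genes were higher on the high-fat diet. Of 32 measured members, 8 rose, 0 fell and 24 did not pass, and 26 rose when adjusted over the list alone. Aldh3a2, a fatty aldehyde dehydrogenase gene, rose by 0.81 (SE 0.13), and Cpt1a, which encodes the enzyme that commits fatty acids to mitochondrial oxidation, rose by 0.47 (SE 0.09). Vnn1 belongs to this list too. Cyp4a14, which encodes a fatty acid omega-hydroxylase, had the value 2.62 (SE 0.81) and did not pass (adjusted p = 0.101), with HFD mice spread from log2 5.79 to 11.31. The list had a median change of 0.33 and an adjusted p of 3.08e-19 by camera, against an adjusted p of 0.0838 with an estimated correlation. Its level was higher in the HFD mouse in 24 of 25 pairs of an HFD and an SD mouse (exact permutation p = 0.0159, 0.127 adjusted over 32 lists).

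Lipid droplet and fat uptake genes gave 6 rises, 1 fall and 17 members that did not pass among 24, or 12 rises and 3 falls adjusted over the list alone. Cd36 and Plin4, which encodes a lipid droplet coat protein, rose, the latter by 0.91 (SE 0.17), while its relative Plin3 fell by 0.47 (SE 0.08). The list passed camera (adjusted p = 3.61e-06), with an adjusted p of 0.0804 with an estimated correlation. In the list of fatty acid and triglyceride synthesis 3 of 21 members fell, namely Acss2 (-0.75), Acly (-0.62) and Acacb (-1.13), 0 rose and 18 did not pass, while 6 fell adjusted over the list alone (camera adjusted p = 0.000942, and adjusted p = 0.763 with an estimated correlation). The call of Acly was lost for 6 of the 10 arrays left out in turn and that of Acacb for 8. Among the genes fixed in advance, Fasn (-0.40), Scd1 (-0.31) and Srebf1 (0.00) did not pass.

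**Figure D2:**
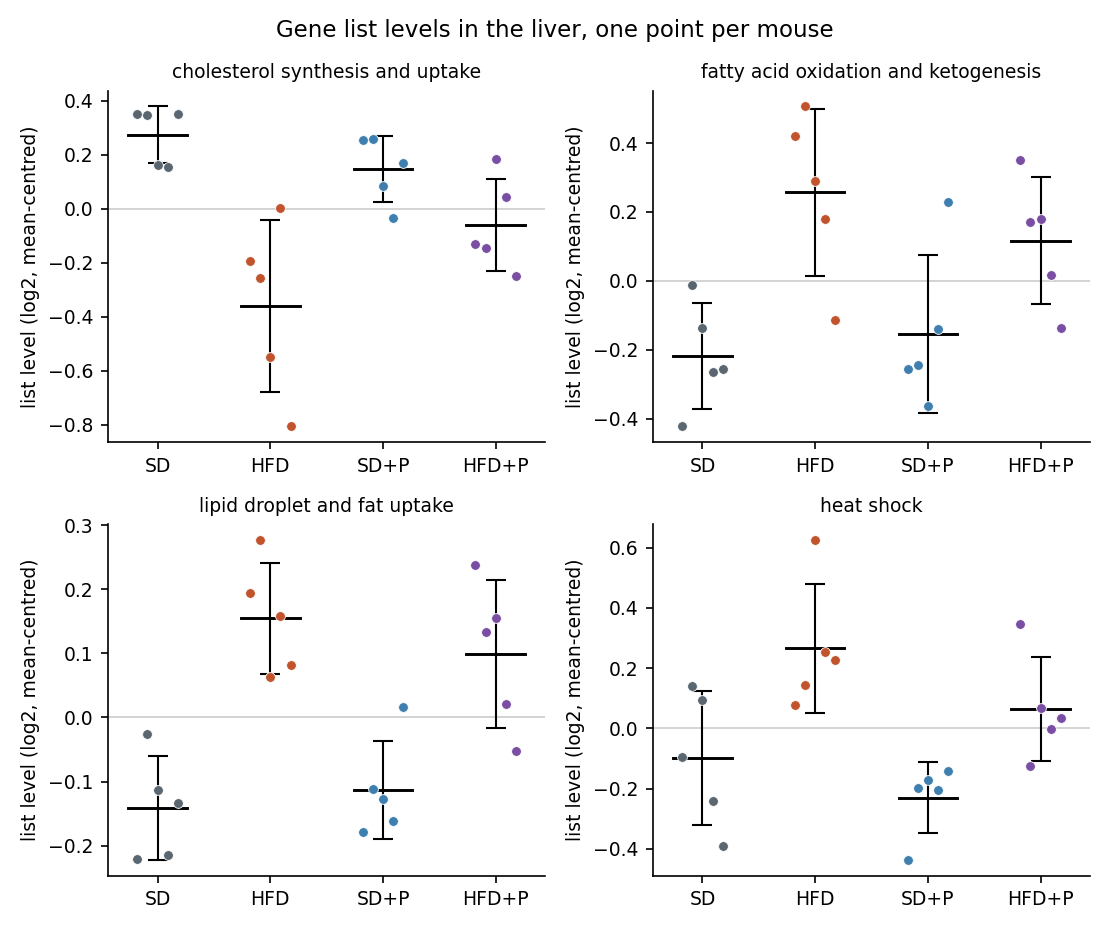
Level of 4 gene lists (vertical axis, mean over members of log2 value minus the gene's mean over all arrays) in each of the 4 groups (horizontal axis); each point is 1 mouse, the horizontal line is the group mean and the bar is 1 standard deviation (n = 5). The cholesterol synthesis level runs from 0.16 to 0.35 in SD mice and from -0.81 to 0.00 in HFD mice.

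Heat shock genes rose on the high-fat diet in 5 of 16 members, with 0 falls and 11 that did not pass (7 rose adjusted over the list alone). Hspa1a rose by 1.22 (SE 0.19), the co-chaperone gene Dnajb1 by 0.93 (SE 0.15) and the constitutive chaperone gene Hspa8 by 0.29 (SE 0.06). The list had a camera adjusted p of 3.16e-07 and an adjusted p of 0.229 with an estimated correlation. Drug and xenobiotic metabolism gave 7 falls, 1 rise and 23 members that did not pass among 31, or 10 falls and 2 rises adjusted over the list alone. The rise was Cyp2b9, and the falls included Cyp2c55 and the glutathione transferase gene Gstm3 (-0.76), whose other probe set gave -1.56 (camera adjusted p = 0.0133, and adjusted p = 0.548 with an estimated correlation). Bile acid synthesis and transport gave 2 falls, Cyp27a1 (-0.29) and Cyp2c70 (-0.32), and 1 rise, the phospholipid exporter gene Abcb4 (0.43), with 22 of 25 members not passing, or 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.548 with an estimated correlation). That list did not pass without SD mouse 3 (adjusted p = 0.0881), HFD mouse 1 (0.134) or HFD mouse 2 (0.0782), and the calls of Cyp2c70 and Abcb4 were lost for 6 and 5 of the 10 arrays left out in turn. Cyp7a1, the rate-limiting enzyme of the classical bile acid pathway, had the value -0.31 (SE 0.26) and did not pass.

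Of the markers of other cells, the lymphocyte list was lower in HFD than in SD livers. The 2 of its 16 members that fell were the B cell receptor genes Cd79a (-1.02, SE 0.23) and Cd79b (-0.65, SE 0.12), 14 did not pass, among them Thy1 (-0.40), and 0 rose. The mean of Cd79a was log2 3.14 in HFD mice, under the log2 3.70 limit for dim genes, so the size of its fall is not well measured. Adjusted over the list alone, the count was 2 as well. The list had a camera adjusted p of 0.0139 and an adjusted p of 0.796 with an estimated correlation, and the call of Cd79a was lost for 3 of the 10 arrays left out in turn. Male-biased liver genes gave a median of -0.15 with 0 of 19 members changed, among them Hsd3b5 (-0.35), Gstp1 (-0.23) and Cyp4a12a (-0.21), at a camera adjusted p of 0.017 and an adjusted p of 0.763 with an estimated correlation. The list did not pass without SD mouse 3 (0.0595), HFD mouse 1 (0.204, with a median of -0.08) or HFD mouse 2 (0.163, median -0.09). Female-biased liver genes gave 1 rise, Cyp2b9, and 11 that did not pass, with Ntrk2 at 0.71 and 3 rises adjusted over the list alone, at a camera adjusted p of 0.0282 and an adjusted p of 0.538 with an estimated correlation, and did not pass without HFD mouse 1 (0.071) or HFD mouse 2 (0.0998). The macrophage and Kupffer cell, neutrophil, stellate cell, bile duct, endothelial, adipocyte, pancreas and red cell lists were not called, and 0 of their members passed. Adgre1 (-0.02), Tnf (-0.13), Tlr4 (0.04), Saa1 (0.21) and Pck1 (0.02) did not pass either.

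Of the 32 lists, 10 passed camera between HFD and SD, 4 up and 6 down, and 0 with an estimated correlation. The balance of rises and falls in the diet comparison depended on scaling: quantile normalising the values again gave 156 rises and 166 falls, and shifting each array to 1 common 75th percentile gave 151 and 169. Calls numbered 169 without SD mouse 6, 190 without SD mouse 5, 195 without HFD mouse 5, 203 without HFD mouse 8 and 208 without HFD mouse 2, and array weights gave 674.

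The diet effect was also measured in mice that received the probiotic. The group means came from 10 arrays other than those of the first comparison, while the variances of both came from the 1 fit to all 20 arrays. Prss8 was again lower on the high-fat diet (-1.59, SE 0.16) and Mfsd2a again higher (2.66, SE 0.34). Also among the 5 genes with the smallest p were Bmp4 (-1.03, SE 0.13), which encodes a secreted growth factor, the melatonin receptor gene Mtnr1a (1.13, SE 0.15), and Il22ra1 (-1.38, SE 0.19), a subunit gene of the interleukin 22 receptor whose other probe set gave -0.61. Fatty acid oxidation genes rose in 11 of 32 members, with 0 falls, and cholesterol synthesis genes fell in 4 of 20, with 0 rises. Adjusted over the list alone, 18 of the former rose, and 5 of the latter fell and 1 rose. Both lists passed camera, with adjusted p of 9.7e-10 and 0.00801, and neither with an estimated correlation (adjusted p = 0.872 for each). Their levels differed in the same direction in 21 of 25 pairs of mice each. The exact permutation p was 0.0794 for fatty acid oxidation and 0.0714 for cholesterol synthesis, so chance division of these 10 mice is not excluded for either list.

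Between HFD+P and SD+P 1165 genes changed, 484 up and 681 down. Of the genes called in the 2 diet comparisons, 45 rose in both, against 3.8 expected for independent lists, and 80 fell in both, against 8.9 expected, while 0 went opposite ways. The shared variances make the expected numbers a rough reference. With each comparison fitted on its own 10 arrays, a test chosen after seeing the data, 27 rose in both against 2.1 expected, 56 fell in both against 4.5 expected, and 0 went opposite ways. Of the 313 genes called between HFD and SD, 282 had the same sign between HFD+P and SD+P. Across all genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson r of 0.403. Shifting each array to a common 75th percentile gave 636 rises and 548 falls. Calls numbered 533 with only the arrays compared in the fit and 1759 with array weights, 570 without SD+P mouse 6, 705 without SD+P mouse 7, 626 without HFD+P mouse 5, 644 without HFD+P mouse 6 and 1800 without HFD+P mouse 8.

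**Figure D3:**
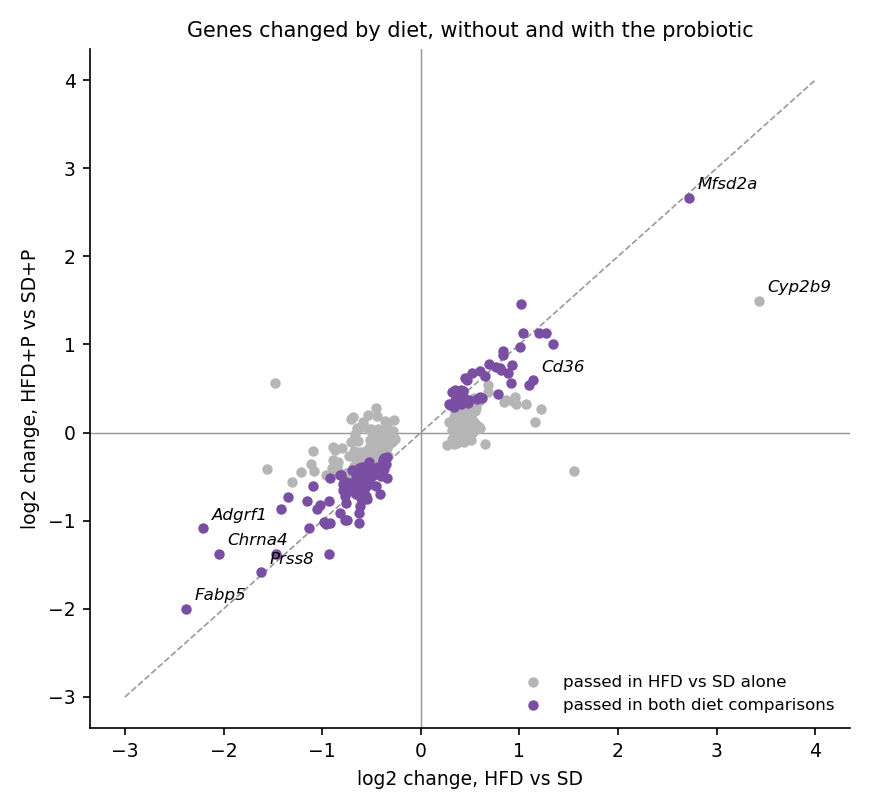
Log2 change from SD to HFD (horizontal axis) against log2 change from SD+P to HFD+P (vertical axis) for the 313 genes called in the former comparison, 1 point per gene; purple points, 125 in number, passed in both comparisons, and the dashed line marks equal change. The sign was the same for 282 genes, and Mfsd2a and Prss8 lie close to the line.

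The next comparison asked what the probiotic did in mice on the high-fat diet. Transcripts that were higher in HFD+P than in HFD livers included Commd7 (0.96, SE 0.20), the spliceosome core protein gene Snrpb (0.85, SE 0.15), Nme6 (0.76, SE 0.15), Tmem203 (0.70, SE 0.12) and Mif, the macrophage migration inhibitory factor gene (0.56, SE 0.11). Lower transcripts included Banp (-0.82, SE 0.15), the La-related gene Larp1b (-0.62, SE 0.13) and the butyrylcholinesterase gene Bche (-0.46, SE 0.09). These changes were under 2-fold, the largest being the 1.95-fold rise of Commd7.

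In all, 21 genes passed in this comparison, 14 up and 7 down, each at an adjusted p of 0.0497 by limma. The other named rises were Rnasek (0.67), Zfp414 (0.64) and Imp3 (0.57), a component of the small-subunit processome. The other falls were the peroxisomal hydrolase gene Nudt12 (-0.47), Sos1 (-0.47), which encodes a Ras exchange factor, the poly(A) polymerase gene Tent4b (-0.46) and the ubiquitin ligase gene Smurf2 (-0.40). The second probe sets of Larp1b and Smurf2 gave smaller values, at -0.29 and -0.17. Across genes, the change correlated with genomic length at r = -0.239, shorter genes being higher in HFD+P. The calls were sensitive to the arrays and genes in the fit: 0 genes passed with no filter on dim genes, with only the arrays compared, with the gene length trend removed, without HFD+P mice 6 and 8 together, or without any 1 of HFD+P mice 4, 5 and 6 and HFD mice 1, 2 and 8. The count was 4 without HFD mouse 5, 5 without HFD mouse 6, 173 without HFD+P mouse 2, 110 without HFD+P mouse 8, 57 with the lowest 50% of genes left out, and 113 with array weights.

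**Figure D4:**
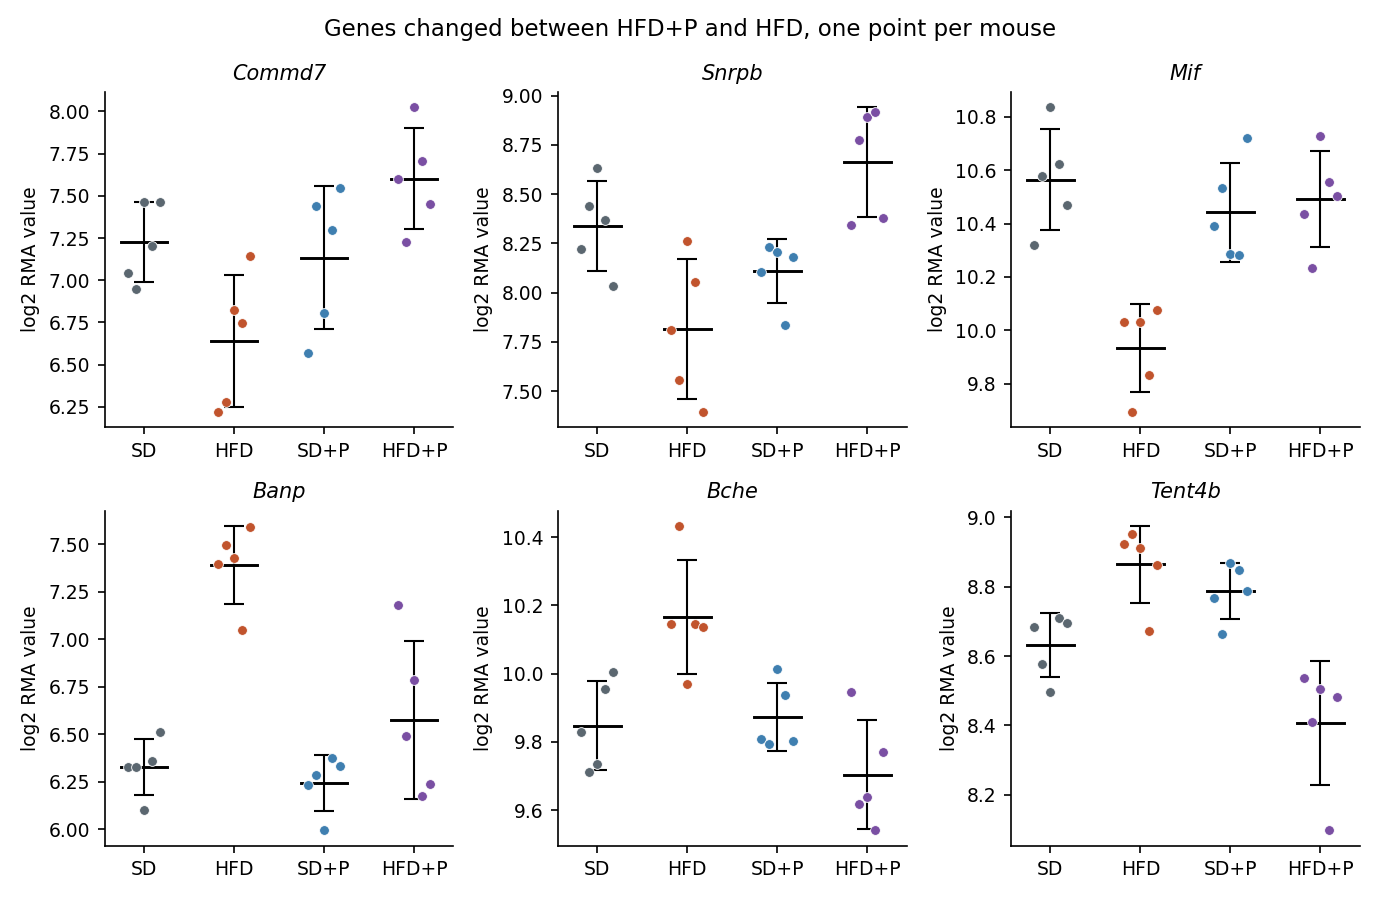
Log2 RMA values (vertical axis) of 6 genes called between HFD+P and HFD in each of the 4 groups (horizontal axis); each point is 1 mouse, the horizontal line is the group mean and the bar is 1 standard deviation (n = 5). Banp is the 1 gene shown whose HFD+P values, from 6.17 to 7.18, overlap those of HFD mice, from 7.05 to 7.59.

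Cholesterol synthesis and uptake genes had a median log2 change of 0.29, with 19 of 20 members higher in HFD+P than in HFD. None passed over all genes, and 8 rose when adjusted over the list alone. Insig1 had the value 0.37 (SE 0.10), Fdps 0.44 (SE 0.13) and Dhcr7 0.36 (SE 0.11). The list passed camera at an adjusted p of 5.75e-07, with an adjusted p of 0.791 with an estimated correlation. Heat shock genes had a median of -0.21 with 0 of 16 members passing, or 2 falls adjusted over the list alone, Hspa1a being at -0.86 (SE 0.19) and Dnajb1 at -0.67 (SE 0.15), at a camera adjusted p of 0.0105 and an adjusted p of 0.791 with an estimated correlation, and the list did not pass without HFD mouse 5 (0.0511), where the median was -0.09. Cd36 (-0.44), Cyp4a14 (-1.27), Cpt1a (-0.12), Fasn (-0.09), Scd1 (0.03), Srebf1 (-0.08), Cyp7a1 (-0.29) and Pck1 (-0.08) did not pass.

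Immune cell markers were higher in the HFD+P group mean, with 0 members passing over all genes or adjusted over the list alone. The medians were 0.22 over 25 macrophage and Kupffer cell markers, among them C1qa (0.50), Tyrobp (0.49) and Fcgr3 (0.45), 0.24 over 16 lymphocyte markers, among them Cd79b (0.35), Cd79a (0.48, with both means under the limit for dim genes) and Cd8a (0.25), and 0.53 over 7 genes of antigen presentation class II, among them H2-Aa (0.77), Cd74 (0.73) and H2-Eb1 (0.53). Their camera adjusted p values were 0.00247, 0.0132 and 0.0182, and each had an adjusted p of 0.791 with an estimated correlation. HFD+P mouse 8 carried the highest level of these lists. Without that mouse the medians were 0.06, 0.02 and 0.11 and the adjusted p values 0.481, 0.8 and 0.875, and antigen presentation class II did not pass without HFD mouse 5 either (0.0511).

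Further lists passed camera between HFD+P and HFD, each with 0 members passing over all genes and an adjusted p of 0.791 with an estimated correlation. Adjusted over the list alone, 3 male-biased, 2 immediate early, 1 cell cycle and 1 oxidative phosphorylation gene rose, 1 endothelial and 1 female-biased gene fell, and 0 interferon genes passed. Higher lists were oxidative phosphorylation (median 0.15, adjusted p = 0.0182), with Ndufv1 at 0.34, Ndufa9 at 0.25 and Cyc1 at -0.34, male-biased liver genes (0.10, 0.0182), with Hsd3b5 at 0.46, Nudt7 at 0.33 and Cyp7b1 at 0.62, cell cycle (0.11, 0.0192), with Cenpa at 0.46, Tyms at 0.27 and Rrm2 at 0.41, and immediate early genes (0.20, 0.026), with Ier3 at 0.34, Egr1 at 1.34 and Fosb at -0.22. Lower lists were the interferon response (-0.25, 0.0105), with Irf7 at -0.74 but Bst2 at 0.60 and Psmb9 at 0.41, endothelial markers (-0.12, 0.0132), with Lyve1 at -0.56, Clec4g at -0.22 (-0.09 in its second probe set, which lies under the limit for dim genes) and Ptprb at -0.23, and female-biased liver genes (-0.23, 0.0132), with Cyp2b9 at -1.91, Atp6v0d2 at -0.59 and Acot3 at -0.46. Calls were lost without HFD+P mouse 2 for the interferon response (adjusted p = 0.0522) and endothelial markers (0.152, with a median of -0.05), and without HFD+P mouse 5 for male-biased genes (0.0706, median 0.05). Without HFD+P mouse 6 the adjusted p was 0.0533 for the interferon response, endothelial markers, male-biased and immediate early genes, and 0.417 for oxidative phosphorylation, the medians being -0.17, -0.05, 0.07, 0.14 and 0.12. Without HFD+P mouse 8 it was 0.483 for immediate early genes, whose median was then 0.08, and 0.886 for cell cycle, whose median was then -0.001. Without HFD mouse 1 it was 0.263 for male-biased genes (median 0.05) and 0.0571 for oxidative phosphorylation, without HFD mouse 2 0.169 for male-biased genes (median 0.07), without HFD mouse 5 0.0572 for immediate early genes, and without HFD mouse 6 0.34 for the interferon response (median -0.17). Without HFD mouse 8 it was 0.0976 for the interferon response, 0.11 for immediate early genes, 0.0544 for oxidative phosphorylation and 0.119 for cell cycle. In all, 12 of 32 lists passed camera in this comparison, 8 up and 4 down, and 0 with an estimated correlation. Dnaja1 (-0.28, and -0.06 in its second probe set) of the heat shock list and Adgre1 (0.06), Tnf (0.29), Tlr4 (0.00) and Saa1 (0.15) did not pass.

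**Figure D5:**
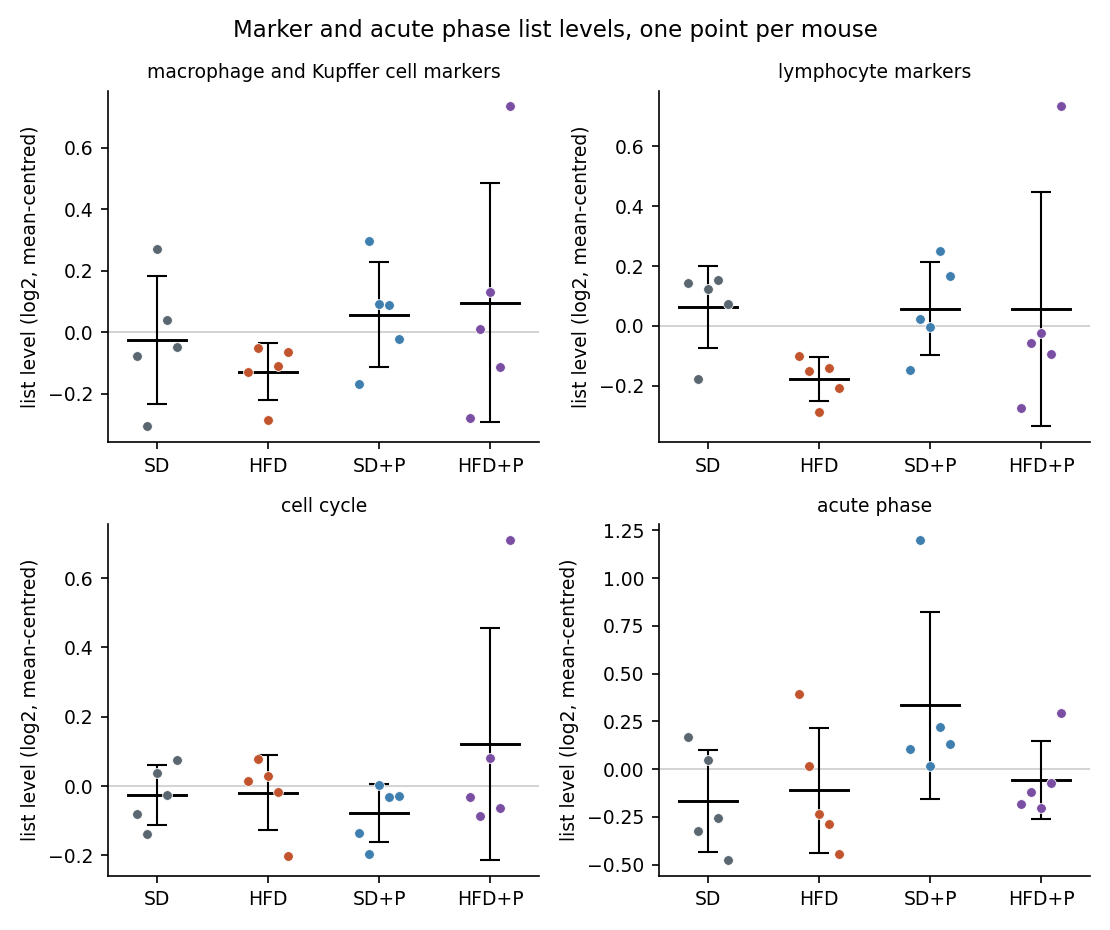
Level of 4 gene lists (vertical axis, mean over members of log2 value minus the gene's mean over all arrays) in each of the 4 groups (horizontal axis); each point is 1 mouse, the horizontal line is the group mean and the bar is 1 standard deviation (n = 5). HFD+P mouse 8 has a macrophage level of 0.73, a lymphocyte level of 0.73 and a cell cycle level of 0.71, and SD+P mouse 3 an acute phase level of 1.2.

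The last comparison of the series design asked whether the probiotic acted on the liver under the standard diet. Acute phase genes had higher values in SD+P than in SD livers, with 27 of 29 members higher and a median log2 change of 0.18. Orm2 had the value 1.61 (SE 0.45), Lcn2, the lipocalin 2 gene, 1.72 (SE 0.52), the metallothionein gene Mt1 1.41 (SE 0.53) and the serum amyloid gene Saa1 1.28 (SE 0.66). None of them passed over all genes, and 2 rose when adjusted over the list alone. The list passed camera at an adjusted p of 6.04e-09, with an adjusted p of 0.915 with an estimated correlation, and SD+P mouse 3 held its highest level. Without that mouse the values were 1.22 for Orm2, 1.28 for Lcn2, 0.82 for Mt1 and 0.60 for Saa1, and the median of the list was 0.10.

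By limma, 0 of 14950 genes passed between SD+P and SD, and 799 genes had an unadjusted p under 0.05, where 747.5 are expected by chance. The genes with the smallest p were Ppp1r3b, a glycogen-targeting subunit gene of protein phosphatase 1 (-0.56, adjusted p = 0.776), Lonrf3 (-0.70, adjusted p = 0.776), Slc17a8 (-1.08), Slc6a19os (0.30), the choline kinase gene Chka (-0.68), the hedgehog pathway receptor gene Smo (0.51), H2-K2 (-0.70), Sec22c (0.43), Sstr2 (0.57), Foxi3 (0.34), Cpne8 (0.66) and Usp17ld (-0.48), with an adjusted p of 0.858 for those after Lonrf3. The count was 1 with only the arrays compared, the gene being Gm4956 (-0.85), and 1 without SD mouse 8, the gene being Lonrf3 (-0.84).

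Camera called 7 lists lower in SD+P than in SD, with 0 members passing over all genes and an adjusted p of 0.915 for each with an estimated correlation. Adjusted over the list alone, 1 cholesterol synthesis and 1 amino acid gene fell, and 0 passed in the other lists. These were the interferon response (median -0.17, adjusted p = 0.00206), with Irf9 at -0.21, Oasl1 at -0.38 and Mx2 at -0.38, bile acid synthesis and transport (-0.06, 0.00337), with Akr1d1 at -0.32, Nr1h4 at -0.28 and Abcb11 at -0.22, amino acid catabolism and the urea cycle (-0.08, 0.00662), with Bhmt at -0.20, Asl at -0.20 and Kynu at -0.16, and fatty acid and triglyceride synthesis (-0.15, 0.00662), with Pnpla3 at -0.41, Thrsp at -0.71 and Gpam at -0.22. The others were oxidative phosphorylation (-0.07, 0.00662), with Atp5a1 at -0.17, Cox5a at -0.16 and Cox5b at -0.17, cholesterol synthesis (-0.10, 0.0249), with Insig1 at -0.36, Mvd at -0.45 and Stard4 at -0.30, and heat shock (-0.09, 0.049), with Chordc1 at -0.53, Hsph1 at -0.66 and Hspa8 at -0.12. With the acute phase list, 8 of 32 lists passed camera, against 4 without SD mouse 3 and 5 without SD+P mouse 6. Single arrays ended the calls of the interferon response (SD+P mouse 2, SD mice 5 and 6, adjusted p from 0.0524 to 0.451), fatty acid synthesis (SD+P mouse 3 and SD mouse 8, 0.0643 and 0.0607) and the amino acid list (SD mouse 3, 0.0941). They also ended those of oxidative phosphorylation (SD+P mice 6 and 7, SD mouse 3, 0.069 to 0.182), cholesterol synthesis (SD+P mice 5 and 6, SD mice 1, 3 and 8, 0.0672 to 0.295) and heat shock (SD+P mice 2 and 6, SD mice 1, 3 and 5, 0.0564 to 0.422). The medians nearest 0 among these were -0.05 for the interferon response (without SD mouse 5), -0.03 for oxidative phosphorylation and -0.04 for heat shock (each without SD mouse 3). Of the genes fixed in advance, Cyp4a14 (1.5), Cpt1a (0.28), Cd36 (0.10), Fasn (-0.30), Srebf1 (-0.12), Scd1 (-0.06), Cyp7a1 (-0.05), Pck1 (0.03), Tnf (-0.09), Tlr4 (-0.03) and Adgre1 (0.06) did not pass.

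The interaction tested whether the probiotic effect differed between the diets. No gene passed in limma, with a smallest adjusted p of 0.178. At an unadjusted p under 0.05 there were 1734 genes, where 747.5 are expected by chance. The smallest p values belonged to Smo (-0.91, SE 0.18), Tent4b (-0.61, SE 0.12), Insig1 (0.73, SE 0.15), Snrpb (1.08, SE 0.22) and Oxnad1 (0.65, SE 0.13), each given as the probiotic effect on the high-fat diet minus that on the standard diet. Without HFD+P mouse 2 the count was 1, the gene being Tmem203 (0.95).

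Whether genes that differed by diet moved back with the probiotic was measured across all genes by the covariance of the change from SD to HFD with the change from HFD to HFD+P. These changes share the HFD arrays with opposite sign, which alone makes the value negative. With the HFD arrays split so that each change used different HFD mice, the covariance was -0.0099 on average over 20 splits and below 0 in all 20, with r = -0.246. The splits reuse the same arrays and are not 20 separate tests. Simulated unchanged groups gave a mean covariance of -0.0009, and 5 of 100 draws gave a value as low as the observed one. The simulated groups held no diet effect, which could widen the draws, so the counts of draws are a rough reference. For r the simulated mean was -0.0302, and 9 of 100 draws were as low. With all HFD arrays in each change, the covariance was -0.0173 against -0.0095 in the simulation, with 6 of 100 draws as low, and r was -0.515 against -0.526, with 58 as low.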

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

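The tests of gene length, of HFD+P mice 6 and 8 together, of the splits counted at an unadjusted p, and the permutation of list levels as a method, were chosen after the results were seen. Leaving out each array in turn was planned, but what it would show for the cholesterol and acute phase lists was written after its results were seen, while the predictions for regrouped arrays and for the permutation p values were written before those numbers were computed.

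The 100 regroupings of the arrays bear on each count of calls. For HFD against SD, 1 of 100 splits, the real one, called as many as 313 genes, and the highest other split called 6. Chance division of these mice is therefore unlikely to account for the count, though not all possible splits were drawn. The same held for HFD+P against SD+P, with 1 of 100 splits, 1165 genes and a highest other of 415. For HFD+P against HFD, 1 of 100 called as many as 21 genes, but the highest other called 16, 7 of 100 gave as many genes as the real 2157 at an unadjusted p under 0.05 (highest other 2549), and the count was 0 without any 1 of 6 of the 10 arrays, so chance division stays open for these calls. For SD+P against SD and the interaction, with 0 calls, all 100 of 100 splits give at least as many whatever the cause, so this count excludes nothing there; the highest others were 1 and 11. At that unadjusted p, 1 of 100 splits gave as many genes as the real 2144 for HFD against SD (highest other 2060) and 1 as many as 3637 for HFD+P against SD+P (3362). For SD+P against SD 25 of 100 gave as many as 799 (1711), and for the interaction 3 as many as 1734 (1900). The median of the other splits was 644 for the interaction. Few splits thus reached its count, but that count names no gene, and counting at an unadjusted p was chosen after the results were seen. Chance division could not be excluded for counts of lists by camera: 26 of 100 splits called as many as the 10 lists for HFD against SD, 43 as many as the 12 for HFD+P against HFD, 35 as many as the 8 for SD+P against SD, 40 as many as the 11 for HFD+P against SD+P, and 78 as many as the 7 for the interaction. The highest others were 16, 18, 19, 19 and 16 lists.

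The 21 genes called between HFD+P and HFD were weighed against gene length and single arrays. With the length trend removed, the change of these genes kept a median of 0.89 of its size. The median size went from 0.53 to 0.49 and the median SE from 0.104 to 0.098. The smooth trend thus held a small part of these changes. A trend of r = -0.239 across all genes could hardly have removed most of changes this large. The test therefore does not decide whether they share a cause with the trend. The calls ended because the adjusted p, at 0.0497 before, rose to at least 0.0682. Without HFD+P mice 6 and 8 the median share kept was 0.94 and the smallest adjusted p 0.0556. Chance division of the mice stays open for the length trend, since 26 of 100 splits gave a correlation as far from 0 as -0.239. The splits reuse the same arrays, so they do not separate chance from a trend carried by a few arrays. Deviations from the group mean correlated with gene length at -0.320 in HFD+P mouse 6 and 0.230 in HFD+P mouse 8. The trend was -0.124 without HFD+P mouse 6 and -0.209 without both, but further from 0 without HFD+P mouse 8 alone. An effect of the probiotic remains open as a hypothesis.

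Cholesterol synthesis genes had higher values in HFD+P than in HFD livers. No 1 array accounts for this, since the median with each array left out in turn was at least 0.237 against 0.290 with all, the lowest being without HFD mouse 8. The list level of HFD mice ran from -0.81 to 0.00, with a standard deviation of 0.318 against 0.171 in HFD+P mice. Leaving out 1 array at a time cannot show whether several low HFD mice together carry the difference. With the smooth trend with gene length removed the median was 0.276, so that trend held little of the difference. The trend is weak across genes, so this does not decide whether the difference shares a cause with it. Chance division of the 10 mice stays open, with an exact permutation p of 0.103 for the list level. The difference is measured against the same HFD arrays that define the fall on the diet, and an effect of the probiotic was not tested separately.

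Acute phase genes had higher values in SD+P than in SD livers, and SD+P mouse 3 stood apart at a level of 1.2, with the other SD+P mice between 0.02 and 0.22. Without that mouse the median was 0.103 against 0.181 with all arrays, which lies between what 1 mouse alone and what the group would give, so the share of that mouse cannot be told apart from a group difference with 5 mice. The exact permutation p of the list level was 0.0556, so chance division is not excluded. An effect of the probiotic was not tested separately from these.

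Further arrays stood apart from their group. HFD+P mouse 8 had a lymphocyte marker level of 0.73, the others lying between -0.27 and -0.02. In that mouse the cell cycle level was 0.71, with the others from -0.08 to 0.08, and the immediate early gene level 0.52, with the others from -0.13 to 0.05. SD mouse 3 had a lymphocyte marker level of -0.18, with the others from 0.07 to 0.15. SD+P mouse 2 had a heat shock level of -0.44, with the others from -0.21 to -0.14. In HFD mouse 5 Hspa1a was at log2 7.24, with the others from 5.63 to 6.06, and in HFD+P mouse 6 Tent4b was at 8.10, with the others from 8.41 to 8.54. In all, 6 of 51 list levels and 2 of 86 gene levels stood apart, where chance gives about 1 in 20.

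By camera, the probiotic effect differed between the diets for 7 lists, each with an adjusted p of 0.937 with an estimated correlation. The median difference, high-fat minus standard diet, was 0.46 for cholesterol synthesis, 0.24 for oxidative phosphorylation, 0.18 for cell cycle, 0.12 for male-biased liver genes and 0.11 for bile acid synthesis and transport. It was -0.23 for acute phase genes and -0.23 for female-biased liver genes. With each of the 20 arrays left out in turn, calls were lost for 9 arrays in the cell cycle list (adjusted p up to 0.915 with a median of 0.02, without HFD+P mouse 8), 4 in the bile acid list (up to 0.0872, without SD+P mouse 3) and 4 in the male-biased list (up to 0.175, without HFD mouse 1), whose median was 0.07 without HFD+P mouse 5. The female-biased list lost its call for 3 arrays (up to 0.0772, without SD+P mouse 7) and the acute phase list for 1 (0.113 with a median of -0.15, without SD+P mouse 3).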

How the results depend on the processing

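Leaving out arrays that stood apart, removing the gene length trend, and permuting list levels were chosen after seeing the data. Of 4431 values of named genes and lists under other settings, 3987 kept their direction and side of the threshold or moved by less than 1 standard deviation, 413 lost and 23 gained significance, 3 moved further and 5 turned direction. These 5 were the cell cycle list between HFD+P and HFD, with medians of 0.002 without HFD+P mice 6 and 8, -0.051 without HFD mouse 8 as well, and from -0.001 (without HFD+P mouse 8) to 0.192 with single arrays left out, immediate early genes in the same comparison at -0.043 without the 3 arrays, and the cell cycle interaction at -0.023 without them. At 0.002 the median kept its sign and the direction of the test turned.

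Genes changed between HFD and SD numbered 674 with array weights. Between HFD+P and HFD they numbered 0 with no filter, 57 with the lowest 50% left out, 0 with only the arrays compared, 113 with array weights, 0 with the length trend removed, 0 without HFD+P mice 6 and 8 and 0 without HFD mouse 8 as well. Leaving out arrays lowers the number compared, but the count was 173 without HFD+P mouse 2 and 110 without HFD+P mouse 8. Without HFD+P mice 6 and 8 together the median SE of the 21 genes stayed at 0.104. The number of arrays alone thus does not set the count, and the cause of these shifts was not tested. SD+P against SD gave 1 with only the arrays compared, and HFD+P against SD+P gave 533 with only those arrays and 1759 with weights. With each array left out in turn the counts ran from 169 to 255, from 0 to 173, from 0 to 1, from 570 to 1800, and from 0 to 1 for the interaction.

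Lists changed between HFD and SD numbered 6 with the lowest 50% of genes left out, 0 with an estimated correlation and 4 by fry. For HFD+P against HFD they were 7 with the length trend removed, and 0 each with an estimated correlation and by fry, and for SD+P against SD 0 each by those 2. Permuted levels gave 0 throughout after adjustment, which the design largely sets: with a smallest p of 0.0079, 6 of 32 lists would have to reach it for any to pass. Without adjustment, the exact permutation p was under 0.05 for 7 of the 10 lists that camera called between HFD and SD. Fatty acid synthesis (0.0873), drug metabolism (0.0794) and male-biased genes (0.246) were the exceptions. The count was 1 of 12 for HFD+P against HFD, 0 of 8 for SD+P against SD and 2 of 11 for HFD+P against SD+P. With arrays left out the lists called by camera ran from 7 to 12, from 8 to 13, and from 4 to 11, the 4 being without SD mouse 3 and 5 without SD+P mouse 6. The planned eBayes settings were not run for lists, since camera moderates variances itself; with a variance trend in camera, tried after seeing the data, the lists numbered 10, 12 and 8 as before. The split covariance ran from -0.0119 to -0.0079 with arrays left out and was -0.0137 with the lowest 50% of genes left out.

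The mouse number as a replicate block gave 175 genes for HFD against SD, 0 for HFD+P against HFD and 1, Slc17a8, for SD+P against SD, with 14 lists there. The labels do not say whether mice of the same number in different groups are linked. Over 20 pairs of the same number the correlation of deviations ran from -0.289 to 0.223, with a median of 0.007 and 5 over 0.1. Pairs of SD+P and SD mice gave 0.092, 0.220 and 0.223, and pairs of HFD+P and HFD mice 0.038, -0.027, 0.220 and 0.189. Pairs of different numbers were not set beside these, so pairing, or a batch behind the numbers, is not excluded. Arrays give no counts, and values near the log2 3.70 limit, such as Cyp2b9 in SD mice and Cyp2c55 and Cd79a in HFD mice, lie near background.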

Other observations

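The genes in this part were chosen after their values were seen, from the lists fixed in advance. In glucose production and insulin signalling, 1 of 25 genes rose and 3 fell between HFD and SD. The glycogen-targeting gene Ppp1r3b rose by 0.45, while the binding protein gene Igfbp2 (-1.09), the coactivator gene Ppargc1a (-0.62) and the kinase gene Sik1 (-0.68) fell. Ppp1r3b (0.62), Ppargc1a (-0.63) and Sik1 (-0.67) passed with the same signs between HFD+P and SD+P. The clock repressor gene Nr1d1 fell on the high-fat diet without the probiotic (-1.15) and with it (-0.78), and the apolipoprotein gene Apoa4 rose in both settings, by 0.69 and 0.77. The stress response gene Ddit3 rose by 0.87 between HFD and SD. By camera at the preset correlation, neither the glucose list (adjusted p = 0.853) nor the clock list (0.798), the lipoprotein list (0.853) or the unfolded protein list (0.124) was called in that comparison.

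Among mice given the probiotic, members of further lists passed between the diets. Drug and xenobiotic metabolism gave 9 falls and 0 rises among 31 members, with 4 genes of the Gstm family among them, Gstm1 (-0.30), Gstm2 (-0.52), Gstm3 (-0.56, and -1.05 in its second probe set) and Gstm4 (-0.34). Oxidative phosphorylation gave 6 rises and 0 falls among 32, led in size by Atp5c1 (0.35). In the urea cycle and amino acid list 4 of 23 rose, Asl (0.38), Oat (0.33), Bhmt (0.28) and Kynu (0.27). Endothelial markers gave 3 falls among 16, Robo4 (-0.55), Cdh5 (-0.52) and Clec4g (-0.41, and -0.05 in a dim second probe set). The camera adjusted p values were 0.00801, 0.00289, 0.0789 and 0.00612, the amino acid list not being called, and each was 0.872 with an estimated correlation. The lipid droplet list gave 5 rises and 1 fall among 24 (0.0162), heat shock 3 rises among 16 (0.00289), the unfolded protein list 2 rises among 25 (0.0461), Herpud1 (0.66) and Dnajb9 (0.84), and cell cycle 1 rise among 25 (0.00457), Cdk1 (0.58). HFD+P mouse 8 had a cell cycle level of 0.71, with the others from -0.08 to 0.08, and the exact permutation p of that list was 0.19. Fatty acid and triglyceride synthesis gave 2 falls among 21 (0.0166), Acss2 (-0.99) and Acacb (-1.08), and acute phase 0 changes among 29 (0.00379), the list being lower in HFD+P with a median of -0.18. SD+P mouse 3 had an acute phase level of 1.2, with the others from 0.02 to 0.22, and the exact permutation p was 0.0714. The adjusted p with an estimated correlation was 0.872 for each of these lists too, and 11 of 32 lists passed camera at the preset correlation.

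Of the 21 genes called between HFD+P and HFD, 6 had also been called between HFD and SD, all with the opposite sign. Mif, Rnasek, Spsb2 and Zfp414 were lower in HFD than in SD and higher in HFD+P than in HFD, and Banp and Nudt12 the reverse. Independent lists would share 0.18 and 0.05 such genes, but the 2 comparisons share the HFD arrays, so the excess is not independent of those arrays.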
